A study of Homo sapiens with 36 samples.

How the data were processed

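RNA levels were measured on 36 Illumina whole-genome bead arrays, 18 from BEAS-2B and 18 from HCT116 cells, each with 10 copper-treated and 8 untreated arrays. According to the labels, RNA was extracted with an RNeasy kit and hybridized as biotin-labelled cRNA. BeadStudio is the software named for the signals, and its version is not given in the sources used here. The authors deposited log2 signals for each probe and array that the file's own header calls non-normalized. Their log2 scale was read from the values, which run from 5.89 to 14.49, with array means between 7.31 and 7.33. Means this close leave open that the authors scaled the arrays to each other before the deposit. Beside each signal the authors deposited a detection p-value of the probe against background, which fell as the signal rose (median Spearman's rho -0.987 within arrays). A second deposited table holds log2 values that were quantile-normalized by the authors. It differed from the first by at most 0.20, each of its 36 arrays matched the array of the same label best, and the lowest correlation of such a pair was 0.9992.

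Signals were put back on the linear scale, corrected for background with the detection p-values, quantile-normalized and returned to log2 with the neqc function of limma 3.58.1 in R 4.3.3, with an offset of 16. Of 43960 probes 13 had missing values and were left out. Gene names and Entrez Gene identifiers came from the annotation of the array and were checked against the RefSeq genes of assembly GRCh38.p14, which held the identifiers of 29474 probes and changed 0 symbols. Of all probes 29511 had 1 gene symbol, 0 had several and 14449 had none. A probe was tested if its detection p was below 0.01 on at least 2 arrays, which 19977 named probes met. Each gene was represented by its probe with the highest mean over all arrays, which gave 14678 genes. Where no copper or no reference array detected the probe, the difference is a bound, with the undetected side at each array's lowest detected value. For a difference of 2 copper effects no bound can be set. No size is given where copper or untreated arrays of either part were all undetected, except for MT1B and MMP3 among flagged results. With members set to bounds, or 0 if undetected on both sides, 10 of 150 list medians moved by over 0.1 and some became 0. Members keep their sign or become 0, so 0 changes of sign show little.

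A single limma model held 1 coefficient for each of 22 groups of line, treatment and time, with 14 residual degrees of freedom. The prior degrees of freedom were 3.44 and the median residual SD was 0.21. Groups with 1 array lend no residual of their own and are assumed to vary like the groups with 2. The number of arrays limits the precision, most of all at 2, 4, 12 and 18 h, where there was 1 untreated array per line. Contrasts were copper minus untreated of the same time, averaged over 5 times, over 2 and 4 h (early) and over 12 and 18 h (late), late minus early, the difference of the averages between lines, and later untreated arrays minus those of 0 h. The moderated test of limma was two-sided. Its p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Replicate numbers do not pair arrays across groups: over 21 pairs of groups per line, the median correlation of the replicate differences was 0.0018 in BEAS-2B and -0.00054 in HCT116.

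For 25 gene lists with 547 members, compiled from general knowledge of these pathways, the camera function tested whether members moved more than other genes, with a preset correlation of 0.01 and adjustment over the lists of a contrast. With an estimated correlation, the average calls that held in both lines were those of metallothioneins, heat shock genes, NRF2 targets, ATF4 targets, immediate early genes, mitosis genes and DNA replication genes. Those of NF-kB and hypoxia genes held in BEAS-2B, and that of YAP genes in HCT116. Between the lines the calls of ATF4, hypoxia, NF-kB, proteasome and YAP genes held, at adjusted p of 0.0015, 6.5e-05, 0.014, 0.014 and 0.014. At single stages, the calls printed all held except those whose second value is given beside them. Colon, mesenchymal, basal airway and leukocyte markers were included to show which of them the lines carry.

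Groups, contrasts, lists, alternatives and the rule for naming genes were set before the data were examined. The rule named the 10 genes with the largest rises and the 10 with the largest falls in each line's average among called genes with the same sign at all 5 times, the 5 largest each way for other contrasts, and up to 4 list members with the smallest adjusted p. It also named a fixed set of metal, heat shock, oxidative and stress genes, of which the report gives a part, and excluded placeholder symbols. Where untreated levels fell into a step after 6 h, the contrast of 12 and 18 h with 0 to 6 h, and the genes shown for it, were chosen after the values were seen. That step was fitted as a further contrast of the same model.

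The alternatives were quantile normalization without background correction, the deposited normalized values, no between-array step, no detection filter, a strict filter that asked for detection on all arrays of a group of 2, the mean of a gene's probes, all untreated arrays of a line as reference, array weights, the replicate number as a block, a trended and robust variance, each line fitted alone, an estimated correlation for the lists, and leaving out each array of a group of 2. A background correction without detection p-values and leaving out each time were added after the data were seen. A block for the slide was not run, since the slides of the arrays are not given in the sources used here. The model was tested on simulated data with 200 changed genes. For averages over 5 times it recovered 71.6% of the changes of 0.5 on the log2 scale in BEAS-2B and 68.7% in HCT116, and 97.0% and 98.5% of those of 1. For the early contrast it recovered 22.4% and 23.9% of the changes of 0.5, and 85.1% and 88.1% of those of 1. The simulation changed fewer genes than the data called, in 1 line at a time, with independent noise of equal spread on every array. Recovery at an adjusted p depends on the share of changed genes, so these rates need not hold for the data. Probes without a gene name were left out of the gene counts, since they belong to no named gene.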

Results

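BEAS-2B is an immortalized human bronchial epithelial cell line, and HCT116 is a human colorectal carcinoma cell line. Both were kept in medium with copper(II) sulphate and harvested over a time course, and RNA levels were measured on 36 Illumina bead arrays, 18 per line. Copper was given at 800 µM to BEAS-2B and at 1400 µM to HCT116, so cell line and dose cannot be told apart. Each line had 10 copper arrays, 2 at each of 2, 4, 6, 12 and 18 h. The 8 untreated arrays of each line were 2 at 0 h, 2 at 6 h and 1 at each of 2, 4, 12 and 18 h. On untreated arrays 42.2% ± 0.63 (SD, n = 8) of probes were detected in BEAS-2B and 41.02% ± 0.93 (SD, n = 8) in HCT116. On the copper arrays of 12 and 18 h the shares were 37.0% ± 0.77 (SD, n = 4) and 34.7% ± 1.65 (SD, n = 4), and the lowest array, at 18 h in HCT116, had 32.2%. After filtering, 14678 genes were tested. Below, a value is the log2 difference of copper minus untreated arrays of the same time, ± is its standard error, and each p is adjusted over all genes tested or, for a list, over the lists. Nothing in the labels says whether 2 arrays of a group came from separate cultures, so the p-values measure a spread between arrays that may be technical.

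Cell line and time in copper were the main axes of the data. The first principal component held 58.6% of the variance and separated the lines, and the second held 21.9% and followed copper. Untreated BEAS-2B arrays lay between -40.5 and -34.4 on the second component, while copper arrays lay at -19.9 and -17.9 at 2 h and at 72.8 and 73.1 at 18 h. Untreated HCT116 arrays lay between -35.9 and -31.7, and their copper arrays moved from -22.8 and -22.4 at 2 h to 74.9 and 78.1 at 18 h. The spread of the copper effect across genes widened from an SD of 0.37 at 2 h to 1.05 at 18 h in BEAS-2B and from 0.33 to 1.03 in HCT116. Genes past a 2-fold difference rose from 1.16% to 26.2% of those tested in BEAS-2B and from 0.87% to 25.2% in HCT116.

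**Figure D1:**
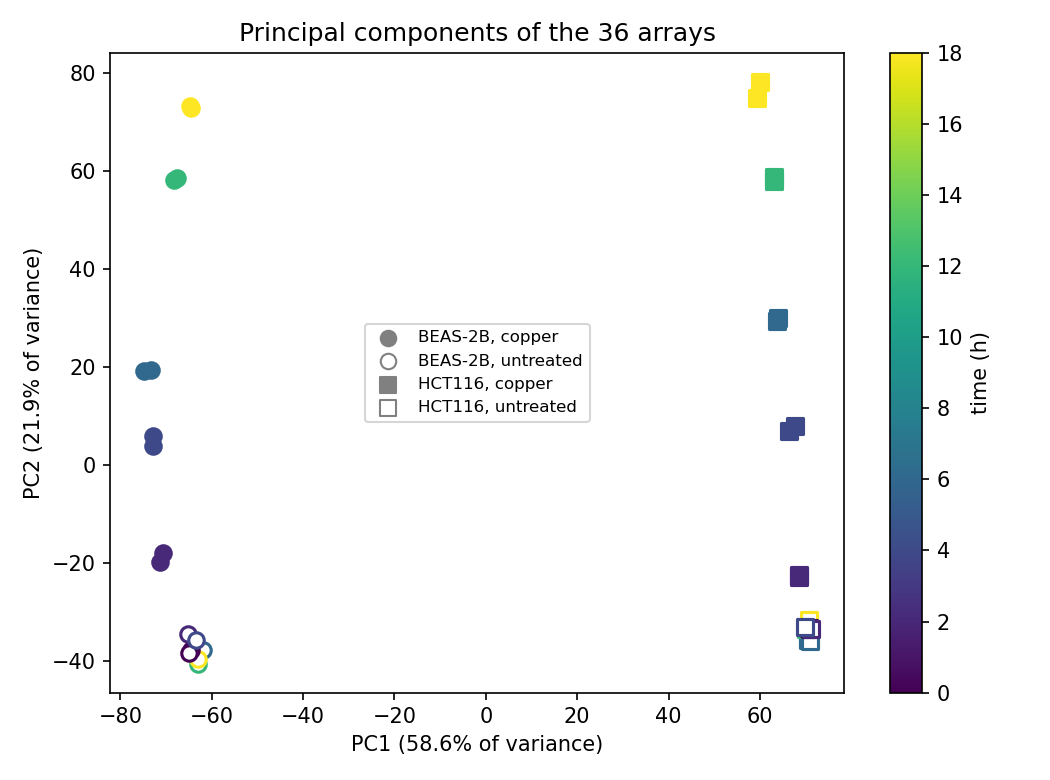
Each point is an array placed by its scores on the first principal component (58.6% of variance, horizontal) and the second (21.9%, vertical), with circles for BEAS-2B, squares for HCT116, open symbols for untreated arrays and colour for time. Copper arrays move up with time in both lines, to 72.8 or more at 18 h, while every untreated array stays at -31.7 or below.

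The comparison of copper with untreated arrays, averaged over the 5 times, asks which transcripts copper changed in each line. Copper raised metallothioneins, heat shock genes and NRF2 targets, together with immediate early and AP-1 genes. It lowered genes of mitosis and DNA replication in both lines. Between the lines, targets of ATF4 and of HIF stood higher in BEAS-2B, and a list of YAP and cytoskeletal genes stood higher in HCT116. In BEAS-2B 7162 genes (48.8%) changed, 2714 up and 4448 down, of which 626 rose and 671 fell by more than 2-fold. In HCT116 6818 genes (46.5%) changed, 2540 up and 4278 down, with 487 and 751 past 2-fold.

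HSPA6 (Entrez Gene 3310, chromosome 1), an inducible Hsp70 chaperone gene, rose in BEAS-2B by 8.36 ± 0.06 on average (adjusted p = 2.6e-23), though 2 of 6 matched untreated arrays detected it, so the size is uncertain. HMOX1 (3162, chromosome 22), which encodes the haem-degrading enzyme haem oxygenase 1, rose by 6.88 ± 0.08, and HSPA7 (3311, chromosome 1) by 6.70 ± 0.10. HSPA6 and HSPA7 are close paralogs, so their probes may share signal. The transcription factor gene FOSB (2354, chromosome 19) rose by 5.63 ± 0.08. FOS, undetected on the matched untreated arrays, was at least 40.1-fold higher with copper, and GADD45G at least 24.9-fold. The chemokine gene CXCL8 rose by 5.01, ARC by 4.80, DNAJA4 by 4.45 and EID3 by 4.38. Of the 6 untreated arrays 2 detected ARC, 4 EID3 and 5 HSPA7. The largest fall was in HPS6 (79803, chromosome 10), a gene for lysosome-related organelle assembly, at -4.07 ± 0.10 (adjusted p = 1.9e-16). It was followed by the pseudouridine synthase gene RPUSD2 (27079, chromosome 15) at -2.90 ± 0.13, TIGD5 at -2.73, CCDC71 at -2.66, FAM217B at -2.63, IMP3 at -2.61, MIR503HG at -2.53, the Wnt receptor gene FZD2 at -2.52, and the cell cycle genes E2F2 at -2.37 and FBXO5 at -2.36. Of the 10 copper arrays 6 detected HPS6, CCDC71 and MIR503HG, 7 RPUSD2, and 8 TIGD5 and FAM217B.

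HCT116 shared many of these genes. HSPA1A (3303, chromosome 6) was at least 60.3-fold higher with copper, HSPA6 at least 49.6-fold, EGR3 at least 17.1-fold and GADD45G at least 16.3-fold, each undetected on the matched untreated arrays. FOS (2353, chromosome 14) rose by 5.74 ± 0.08, FOSB by 5.03, HMOX1 by 4.82, EID3 by 4.74, CXCL8 by 4.32 and JUN by 4.30. HPS6 again fell the most, at -4.32 ± 0.10 (adjusted p = 1.1e-16). The hyaluronan synthase gene HAS3 (3038, chromosome 16) fell by 3.38 on the log2 scale with probes that gave unlike sizes, and TMEM177 (80775, chromosome 2) fell to -3.15. TIGD5 fell to -2.98, the heparan sulphate enzyme gene HS3ST1 to -2.89, RPUSD2 to -2.79, CCDC71 to -2.77, IMP3 to -2.63, the phosphodiesterase gene PDE4B to -2.55 and FJX1 to -2.55. Of the 6 untreated arrays 3 detected EID3 and CXCL8, and of the 10 copper arrays 4 detected CCDC71, 6 HPS6, 8 TMEM177, and 9 TIGD5, HS3ST1, PDE4B and FJX1. Of the genes that rose, 1557 rose in both lines where 470 would be shared if the lines were independent. Of the genes that fell, 2982 fell in both, against 1296. A further 228 genes rose in BEAS-2B and fell in HCT116, and 131 did the reverse. Across genes the average effects of the lines gave Pearson's r = 0.699 and Spearman's rho = 0.636, over 14678 genes that are not independent replicates.

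Metallothioneins are small cysteine-rich proteins that bind copper and zinc. Of 9 measured, 7 rose and 0 fell in BEAS-2B with 2 not called, also when adjusted over the list alone, for a median of 1.67 (list adjusted p = 1.4e-07). MT1X (4501, chromosome 16) rose by 3.23 ± 0.07, MT1G by 2.49, MT1M by 2.33, MT1F by 1.11 and MT2A by 1.00. HCT116 also had 7 rises, 0 falls and 2 not called (8 rises adjusted over the list alone), with a median of 1.51 (list adjusted p = 2.7e-07), and here MT1B rose by 3.65, MT1G by 2.23, MT1X by 1.76, MT1F by 1.51 and MT2A by 0.48. MT1B was detected on 4 of the 6 untreated arrays. The probes of the MT1 genes lie in close paralogs and can share signal. Among 21 copper and zinc transport and copper chaperone genes, the zinc exporter gene SLC30A1 (7779, chromosome 1) rose by 3.24 ± 0.07 in BEAS-2B and 2.81 in HCT116. The list as a whole was not called in either line, with 5 rises, 10 falls and 6 not called in both (list adjusted p = 0.90 and 0.60; adjusted over the list alone 6 and 10 in BEAS-2B, 5 and 12 in HCT116). Its median in BEAS-2B was -0.17 while its mean was 0.02. The zinc importer gene SLC39A14 rose by 1.42 in BEAS-2B. SCO1 and SCO2, which deliver copper to cytochrome c oxidase, fell to -0.97 and -2.13 in BEAS-2B and to -0.96 and -2.48 in HCT116, with SCO2 detected on 8 and 9 of the 10 copper arrays. The copper importer gene SLC31A1 rose by 1.03 and 0.42, the copper pump gene ATP7A by 0.56 and 0.49, and ATP7B stood at -0.17 (adjusted p = 0.22) in BEAS-2B and -0.34 in HCT116. ATP7B was detected on 7 of the 10 copper arrays of HCT116. Its call there was lost without the 12 h or the 18 h arrays (adjusted p = 0.72 and 0.19), and the mean of its probes was 0.049. In BEAS-2B ATP7B was called without the arrays of 2, 4 or 6 h, at adjusted p of 0.020, 0.047 and 0.029. MTF1, the metal-responsive transcription factor gene, rose by 0.72 in HCT116.

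Cytosolic heat shock proteins and their co-chaperones, which keep damaged protein soluble, rose almost throughout the list. In BEAS-2B 28 of 29 rose, 0 fell and 1 was not called, also when adjusted over the list alone (median 1.15, list adjusted p = 3.0e-21), with ZFAND2A at 4.01, DNAJB1 at 3.72, HSPA1B at 3.19, BAG3 at 2.65 and HSPH1 at 1.70. In HCT116 23 rose, 0 fell and 6 were not called (24 rises adjusted over the list alone; median 1.06, list adjusted p = 3.0e-19), with ZFAND2A at 3.73, DNAJB1 at 3.06, BAG3 at 2.09 and HSPA1B at 1.06. Targets of NRF2, which supply glutathione and remove oxidants, rose in both lines. BEAS-2B had 12 rises, 3 falls and 8 not called among 23, the same when adjusted over the list alone (median 0.33, list adjusted p = 7.4e-06), with SLC7A11 at 2.62, SRXN1 at 2.07 and GCLM at 1.90. HCT116 had 14 rises, 2 falls and 7 not called, the same when adjusted over the list alone (median 0.42, list adjusted p = 8.5e-07), with SLC7A11 at 1.91, SRXN1 at 1.74 and GCLM at 1.28, the first of them detected on 5 of the 6 untreated arrays.

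Targets of ATF4, the transcription factor of the integrated stress response, rose in BEAS-2B for 21 of 24 genes, with 1 fall and 2 not called, also when adjusted over the list alone (median 0.90, list adjusted p = 1.2e-14). ATF3 rose by 4.30, TRIB3 by 3.56, PPP1R15A by 3.45, DDIT4 by 3.44 and DDIT3 by 3.27 in that line. In HCT116 11 rose, 3 fell and 10 were not called (13 and 3 adjusted over the list alone; median 0.22, list adjusted p = 1.6e-05), with PPP1R15A at 4.02, ATF3 at 3.49, DDIT3 at 2.92 and TRIB3 at 1.77. Unfolded protein response genes of the endoplasmic reticulum had a lower median than ATF4 targets in BEAS-2B and a higher one in HCT116. No test compared these lists. BEAS-2B had 11 rises, 4 falls and 4 not called among 19 (12 and 4 adjusted over the list alone; median 0.29, list adjusted p = 0.013, adjusted p = 0.076 with an estimated correlation), with DNAJB9 at 1.52, XBP1 at 0.99 and SDF2L1 at -0.65. HCT116 had 10, 3 and 6, the same when adjusted over the list alone (median 0.29, list adjusted p = 0.0090, adjusted p = 0.062 with an estimated correlation), with DNAJB9 at 1.34 and SDF2L1 at -0.98. The chaperone gene HSPA5 rose by 0.44 in BEAS-2B and 0.48 in HCT116.

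Immediate early and AP-1 genes, which encode transcription factors and phosphatases induced within minutes of a stimulus, rose for 21 of 22 genes in BEAS-2B with 0 falls and 1 not called, also when adjusted over the list alone (median 1.70, list adjusted p = 3.0e-21). The phosphatase genes DUSP5 and DUSP1 rose by 3.15 and 2.81 there. In HCT116 18 rose, 3 fell and 1 was not called, also when adjusted over the list alone (median 1.71, list adjusted p = 2.2e-13), with DUSP1 at 3.18. Among 18 NF-kB and inflammatory genes, 12 rose, 2 fell and 4 were not called in BEAS-2B, also when adjusted over the list alone (median 0.80, list adjusted p = 1.2e-05), with IL11 at 3.21 and with CXCL2 at 2.10 and detected on 1 of 6 untreated arrays. In HCT116 5 rose, 2 fell and 11 were not called, also when adjusted over the list alone (median 0.11, list adjusted p = 0.030, adjusted p = 0.088 with an estimated correlation and 0.052 without the 4 h arrays), with PTGS2 at 2.16 and detected on 4 of 6 untreated arrays, IL11 at 1.67 and the inhibitor gene NFKBIA at -1.75.

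All 25 mitosis genes fell in each line, also when adjusted over the list alone, with medians of -0.91 in BEAS-2B (list adjusted p = 3.0e-12) and -0.72 in HCT116 (list adjusted p = 3.2e-10). TOP2A fell to -1.94, AURKA to -1.26, KIF11 to -1.04 and CDK1 to -1.02 in BEAS-2B, and CCNA2 to -1.44, AURKA to -1.41 and CCNB1 to -1.07 in HCT116. Among 23 DNA replication genes, BEAS-2B had 1 rise, 16 falls and 6 not called (1 and 17 adjusted over the list alone; median -0.70, list adjusted p = 1.7e-06) and HCT116 1, 18 and 4, the same when adjusted over the list alone (median -0.67, list adjusted p = 4.8e-06). The replication factor genes MCM10, FEN1 and PCNA stood at -1.66, -1.54 and -1.29 in BEAS-2B and at -1.69, -1.66 and -1.04 in HCT116. Targets of p53 went both ways, with 6 rises, 9 falls and 8 not called among 23 in BEAS-2B (list adjusted p = 0.42) and 8, 6 and 9 in HCT116 (list adjusted p = 0.66), the same when adjusted over the list alone. GADD45A rose by 2.92 and 1.83 and CDKN1A by 1.63 and 0.53, while SESN1, detected on 6 of the 10 copper arrays, fell to -1.17 in BEAS-2B and XPC to -1.04 in HCT116.

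Hypoxia genes, targets of HIF that serve glycolysis and blood supply, rose in BEAS-2B for 13 of 18 with 1 fall and 4 not called, also when adjusted over the list alone (median 0.48, list adjusted p = 3.7e-07). VEGFA rose by 2.80, NDRG1 by 2.67, PFKFB3 by 2.00 and HK2 by 1.81. In HCT116 4 rose, 5 fell and 9 were not called (4 and 6 adjusted over the list alone; list adjusted p = 0.78), with VEGFA at 0.95, ADM at 0.81 and PFKFB4 at -1.53. Cholesterol synthesis genes were not called as a list, with 9 rises, 5 falls and 5 not called among 19 in BEAS-2B (9 and 6 adjusted over the list alone; list adjusted p = 0.074) and 6, 5 and 8 in HCT116 (7 and 5; list adjusted p = 0.10). Without the 12 h arrays the list was called in both, at list p of 0.038 and 0.046. In BEAS-2B it was also called without the 18 h arrays, with the mean of a gene's probes and against all untreated arrays, at list p of 0.011, 0.035 and 0.039. INSIG1 rose by 1.60 and 1.71 and HMGCS1 by 1.11 in BEAS-2B, while SQLE stood at -1.13 in HCT116. Proteasome subunit genes gave 4 rises, 11 falls and 12 not called among 27 in BEAS-2B, the same when adjusted over the list alone (list adjusted p = 0.50), with PSMD12 at 0.59 and PSMA1 at -0.62. HCT116 gave 11, 5 and 11 (12 and 5 adjusted over the list alone; list adjusted p = 0.014, adjusted p = 0.075 with an estimated correlation), with PSMA2 at 1.00 and PSMD12 at 0.73. Lipoylation and iron-sulphur cluster genes, whose proteins copper can damage, gave 3 rises, 9 falls and 6 not called among 18 in BEAS-2B (list adjusted p = 0.074) and 2, 7 and 9 in HCT116 (list adjusted p = 0.29), the same when adjusted over the list alone. The list was called in BEAS-2B without the 12 h arrays, without the detection filter and with the mean of a gene's probes, at list p of 0.047, 0.026 and 0.021. ISCA2 fell to -1.13 and -0.93, and GLRX5 to -0.81 in BEAS-2B, where 8 of the 10 copper arrays detected ISCA2.

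BCL2 family and caspase genes gave 6 rises, 7 falls and 6 not called among 19 in BEAS-2B (7 and 7 adjusted over the list alone; list adjusted p = 0.40) and 7, 5 and 7 in HCT116 (7 and 6; list adjusted p = 0.27). The death-promoting genes PMAIP1 and HRK rose by 3.25 and 2.52 in BEAS-2B, and PMAIP1 by 1.20 in HCT116. HRK was detected on 5 of the 6 untreated arrays. Autophagy genes gave 6 rises, 2 falls and 9 not called among 17 in BEAS-2B, the same when adjusted over the list alone (list adjusted p = 0.052). The list was called there without the 12 h or 18 h arrays or replicate 2 of the copper arrays at 2 h, at list p of 0.049, 0.0498 and 0.045. It was also called without the detection filter, with the strict filter and with the mean of a gene's probes, at 0.027, 0.047 and 0.031. Autophagy genes gave 8, 3 and 6 in HCT116 (9 and 3; list adjusted p = 0.011, adjusted p = 0.081 with an estimated correlation). MAP1LC3B rose by 2.47 and 2.18 and GABARAPL1 by 2.31 and 2.28, while VPS18 stood at -1.65 in HCT116 and was detected on 4 of the 10 copper arrays. Ribosomal protein genes barely moved, with 2 rises, 3 falls and 24 not called among 29 in BEAS-2B (list adjusted p = 0.98) and 2, 0 and 27 in HCT116 (list adjusted p = 0.54), the same when adjusted over the list alone, and with RPS23 at 0.36 in BEAS-2B. Ribosome biogenesis genes gave 4 rises, 12 falls and 6 not called among 22 in BEAS-2B (list adjusted p = 0.44) and 6, 10 and 6 in HCT116 (list adjusted p = 0.77), the same when adjusted over the list alone. RRS1 fell to -1.34 and -1.38, and NOP58 rose by 1.04 in BEAS-2B. YAP and cytoskeletal genes were not called in BEAS-2B, with 3 rises, 4 falls and 10 not called among 17, the same when adjusted over the list alone (list adjusted p = 0.63), LATS2 at 1.90 and ANKRD1 at -1.49. In HCT116 9 rose, 0 fell and 8 were not called (10 and 0 adjusted over the list alone; median 0.26, list adjusted p = 7.8e-06), with CCN2 at 3.85, THBS1 at 3.74, CCN1 at 3.51 and TAGLN at 2.98, the last from probes that ranged from no change upwards.

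Replication-dependent histone genes gave 6 rises, 2 falls and 7 not called among 15 in each line (7 and 2 adjusted over the list alone in BEAS-2B, 6 and 2 in HCT116; list adjusted p = 0.052 in BEAS-2B and 0.0063 in HCT116, adjusted p = 0.050 with an estimated correlation). The list was called in BEAS-2B without the arrays of 2, 4 or 6 h, at list p of 0.035, 0.030 and 0.016. It was called as well with quantile normalization alone, the deposited normalized values and the line fitted alone, at list p of 0.046, 0.046 and 0.047. With the mean of a gene's probes, no detection filter and all untreated arrays the list p was 0.031, 0.032 and 0.032. It was also called there, at list p of 0.033 to 0.048, without replicate 1 of 12 h copper, replicate 2 of 18 h copper or replicate 2 of 6 h untreated BEAS-2B, or without either replicate of 18 h copper or 6 h untreated HCT116. H2AC18, whose probe also fits H2AC19, rose by 2.25 and 2.19, and H4C3 fell to -1.09 in BEAS-2B. The lists of cell type markers were not called in BEAS-2B. Colon markers gave 2 rises, 1 fall and 9 not called among 12 in BEAS-2B (list adjusted p = 0.44) and 2, 3 and 7 in HCT116 (list adjusted p = 0.84), with KRT18 at 0.82 and with CDX2 at -1.76 and detected on 6 of the 10 copper arrays in HCT116. Mesenchymal markers gave 6, 4 and 6 among 16 in BEAS-2B (list adjusted p = 0.89) and 0, 2 and 14 in HCT116 (list adjusted p = 0.83), with CAV1 at -0.64 and -0.66 and COL1A1 at -0.83 in BEAS-2B. Basal airway markers gave 2, 1 and 4 among 7 in BEAS-2B (list adjusted p = 0.24) and 3, 0 and 4 in HCT116 (list adjusted p = 0.018, adjusted p = 0.072 with an estimated correlation), with LAMB3 at 1.12 and 2.08 from probes that ranged down to no change, and SFN at 1.22 in HCT116. Leukocyte markers gave 3, 0 and 5 among 8 in each line (list adjusted p = 0.085 in BEAS-2B and 0.030 in HCT116, adjusted p = 0.14 with an estimated correlation, 0.051 without the 4 h arrays and 0.11 with the mean of a gene's probes), with CD14 at 0.85 and 1.90, detected on 2 of the 6 untreated arrays of HCT116. The counts of the 4 marker lists were the same when adjusted over the list alone. Median and mean differed in sign for p53 targets, YAP genes and mesenchymal markers in BEAS-2B, and for BCL2 genes, ribosomal proteins, colon markers and mesenchymal markers in HCT116. For p53 targets and hypoxia genes in HCT116 the median and mean were below 0 and the list test pointed up, and none of these lists was called.

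**Figure D2:**
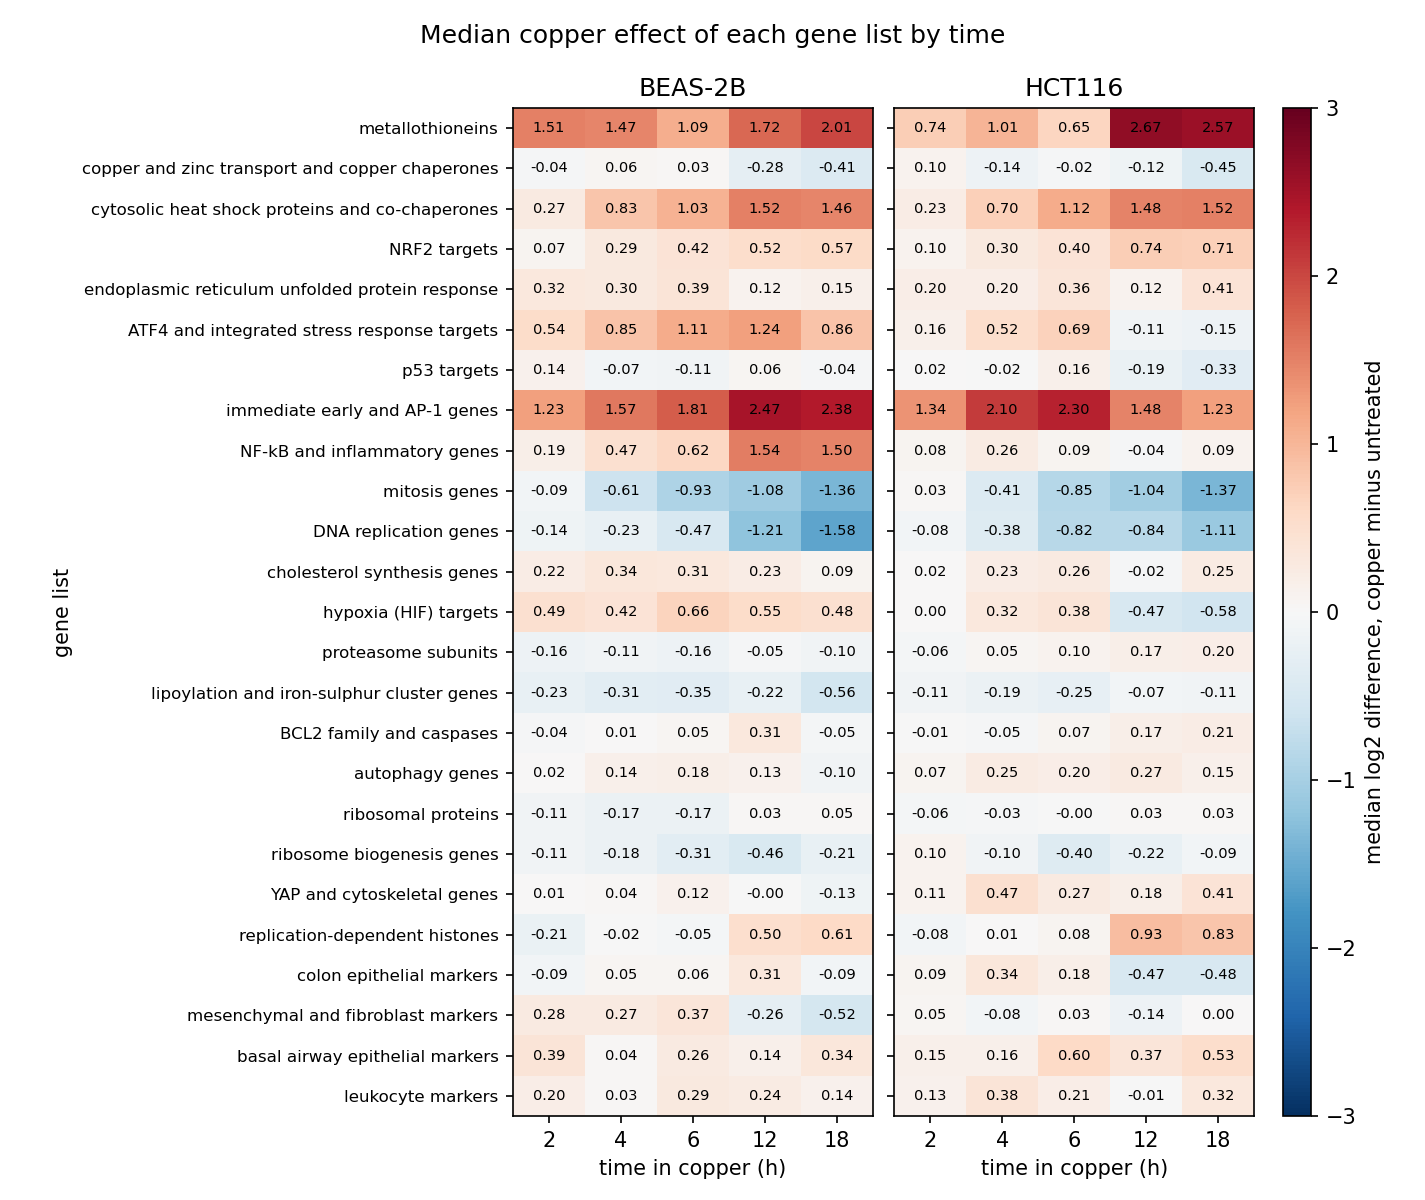
Each cell gives the median log2 difference, copper minus untreated, of a gene list (vertical axis) at a time in copper (h, horizontal axis), with BEAS-2B on the left and HCT116 on the right. Mitosis genes go from -0.09 at 2 h to -1.36 at 18 h in BEAS-2B and from 0.03 to -1.37 in HCT116, and ATF4 targets in HCT116 go from 0.69 at 6 h to -0.11 at 12 h, where untreated levels of these genes were higher.

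The comparison at 2 and 4 h asks what copper changed within hours. Heat shock, metallothionein and early response genes were already up in both lines, and mitosis genes fell in BEAS-2B, for 12 of 25 (list adjusted p = 4.4e-07). BEAS-2B changed more genes than HCT116 at this stage. In BEAS-2B 2416 genes changed, 1162 up and 1254 down, with 237 and 106 past 2-fold. In HCT116 1326 changed, 668 up and 658 down, with 165 and 75 past 2-fold. HSPA6 was at least 142-fold higher in copper-treated BEAS-2B, HMOX1 rose by 6.33 ± 0.13, FOSB by 4.54, HSPA7, detected on 1 of 2 untreated arrays, by 4.49 and EID3 by 3.75. FBXO5 fell to -2.66, HPS6 to -2.44, RPUSD2 to -2.05, TMEM177 to -1.92 and TIGD5 to -1.79. FOS rose by 5.03 ± 0.13 in HCT116, FOSB by 4.44, HMOX1 by 4.14 and JUN by 3.93, and EGR3 was at least 12.7-fold higher. HPS6 fell to -2.30 in that line, RPUSD2 to -1.75, the death adaptor gene FADD to -1.65, TIGD5 to -1.60 and HAS3 to -1.55. The lines shared 423 rises, where 52.9 would be shared by independence, and 379 falls, against 56.2.

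Where a list has 1 pair of counts here and at later times, the counts adjusted over the list alone were the same. Among the lists at 2 and 4 h, all 22 immediate early genes rose in BEAS-2B (median 1.42, list adjusted p = 7.8e-38), and 17 rose, 1 fell and 4 were not called in HCT116 (median 1.84, list adjusted p = 4.5e-40), with DUSP1 at 2.36 and 3.52 and EGR1 at 3.85 in HCT116. Heat shock genes gave 18 rises and 0 falls in BEAS-2B (20 adjusted over the list alone; median 0.63) and 16 and 0 in HCT116 (19; median 0.47), with DNAJB1 at 3.02 and 2.23. Metallothioneins gave 7 rises and 0 falls in each line, with MT1X at 3.07 and 1.10. ATF4 targets gave 16 rises, 1 fall and 7 not called in BEAS-2B (17 and 2 adjusted over the list alone; list adjusted p = 2.6e-18) and 11, 0 and 13 in HCT116 (11 and 1; list adjusted p = 9.6e-17), with DDIT4 at 3.34 and 3.46. The unfolded protein response was called at this stage in both lines, at 8 rises and 1 fall in BEAS-2B (9 and 2 adjusted over the list alone; list adjusted p = 2.5e-04) and 5 and 1 in HCT116 (6 and 1; list adjusted p = 0.0014), with HYOU1 at 0.69 and 0.66. Cholesterol synthesis genes gave 8 rises and 0 falls in BEAS-2B (9 and 0 adjusted over the list alone; list adjusted p = 8.0e-05), with INSIG1 at 1.48 and HMGCS1 at 0.90, and 4 rises and 1 fall in HCT116 (6 and 1; list adjusted p = 0.077, and 0.044 without replicate 1 of copper-treated HCT116 at 4 h, 0.049 with the line fitted alone and 0.023 with the mean of a gene's probes). Hypoxia genes gave 9 rises and 0 falls in BEAS-2B (list adjusted p = 7.4e-09) and 3 and 0 in HCT116 (6 and 1 adjusted over the list alone; list adjusted p = 0.0033, and 0.15 against all untreated arrays), with VEGFA at 2.10 and 1.49. Mitosis genes gave 12 falls and 0 rises in BEAS-2B (14 falls adjusted over the list alone; list adjusted p = 4.4e-07) and 6 and 0 in HCT116 (7; list adjusted p = 0.0031, adjusted p = 0.12 with an estimated correlation), with CDCA8 at -0.82 and -0.61. Mesenchymal markers gave 4 rises and 0 falls in BEAS-2B (8 and 2 adjusted over the list alone; list adjusted p = 0.014, and 0.062 without the between-array step), with PDGFRB at 0.65.

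The comparison at 12 and 18 h asks what prolonged copper changed. Falls outnumbered rises in both lines, and the fall of mitosis and replication genes deepened. Histone genes rose. In BEAS-2B 7262 genes changed, 2670 up and 4592 down, with 1235 and 2041 past 2-fold. In HCT116 7063 changed, 2606 up and 4457 down, with 1082 and 2028 past 2-fold. Without the step that gives all arrays the same distribution, the median of all genes moved to -0.11 in BEAS-2B and -0.19 in HCT116, so falls are stated relative to the other genes on the array. In BEAS-2B HSPA6 rose by 9.02 ± 0.11, HSPA7 by 8.32 and RASD1, detected on 1 of 2 untreated arrays, by 7.81, and the growth arrest gene GADD45G was at least 347-fold higher and the signalling regulator gene RGS2 at least 288-fold. HPS6 was at least 42.4-fold lower and MIR503HG at least 19.1-fold lower, each undetected on the copper arrays, while FZD2 fell to -4.16, SLF2 to -3.99 and SLC61A1 to -3.84, the last pair detected on 3 and 1 of the 4 copper arrays. In HCT116 HSPA1A was at least 343-fold higher, HSPA6 at least 263-fold, GADD45G at least 230-fold and HSPA7 at least 87.5-fold, and FOS rose by 6.63. HPS6 was at least 59.4-fold lower, HAS3 fell to -5.27, HS3ST1 to -5.16, OXLD1 to -4.27 and TMEM177 to -4.14, with HS3ST1 and TMEM177 detected on 3 and 2 of the 4 copper arrays. The lines shared 1512 rises, against 474 by independence, and 3028 falls, against 1394.

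Late in copper, 27 of 29 heat shock genes rose in BEAS-2B and 24 in HCT116, with 0 falls (25 in HCT116 adjusted over the list alone; medians 1.62 and 1.53) and with ZFAND2A at 5.16 and 4.53. Metallothioneins gave 7 rises in each line, with medians of 1.87 and 2.65, and MT1B was at least 35.2-fold higher in HCT116. NRF2 targets gave 12 rises and 3 falls in BEAS-2B and 15 and 2 in HCT116 (16 and 2 adjusted over the list alone), with HMOX1 at 7.28 and 5.49. Mitosis genes gave 24 falls and 1 not called in BEAS-2B (median -1.24, list adjusted p = 4.7e-11) and 23 and 2 in HCT116 (24 falls adjusted over the list alone; median -1.42, list adjusted p = 1.4e-09), with TOP2A at -3.37 in BEAS-2B and KIF20A at -2.36 in HCT116. DNA replication genes gave 3 rises and 19 falls in BEAS-2B (median -1.31) and 2 and 18 in HCT116 (median -0.99), with FEN1 at -2.34 and -2.39. Histone genes gave 8 rises, 1 fall and 6 not called in BEAS-2B (median 0.62, list adjusted p = 0.0026) and 10, 1 and 4 in HCT116 (11 and 1 adjusted over the list alone; median 0.76, list adjusted p = 1.9e-04), with H2AC18 at 5.66 and 3.98. NF-kB genes gave 12 rises and 3 falls in BEAS-2B (median 1.52), with CXCL8 at 7.46 and IL11 at 4.83. They were not called in HCT116 (4 and 3, list adjusted p = 0.11), where CXCL8 stood at 5.45 from probes of unlike size. ATF4 targets gave 17 rises, 1 fall and 6 not called in BEAS-2B (median 1.05, list adjusted p = 4.7e-11) with TRIB3 at 4.18. In HCT116 they gave 6 rises, 11 falls and 7 not called, with a median of -0.13 and a mean of 0.18 (list adjusted p = 0.67), TRIB3 at 1.16 and SESN2 at 2.65. Hypoxia genes gave 10 rises and 1 fall in BEAS-2B (11 and 1 adjusted over the list alone; list adjusted p = 1.7e-05), with NDRG1 at 3.71. In HCT116 they gave 1 rise, 13 falls and 4 not called (median -0.50, list adjusted p = 0.020, and 0.058 with the mean of a gene's probes), with PFKFB4 at -3.20 and SLC2A1 at -1.17.

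The falls of ATF4 and hypoxia targets in HCT116 rest on their untreated arrays of 12 and 18 h, where these genes stood higher than before. DDIT4 was at 9.03 on untreated HCT116 arrays at 6 h and at 12.90 and 12.85 at 12 and 18 h, and its copper difference went from 3.40 at 6 h to -1.39 and -1.60. Against all 8 untreated arrays of the line, the late mean of ATF4 targets was 0.89 (list adjusted p = 1.9e-04) and that of hypoxia targets -0.07 (list adjusted p = 0.57). In BEAS-2B part of the late NF-kB rise lies in the untreated arrays, where CXCL8 went from 9.10 at 6 h to 6.55 and 6.67 at 12 and 18 h. Against all 8 untreated arrays of that line the late mean of NF-kB genes was 1.27 (list adjusted p = 9.0e-05), where it was 1.59 with matched arrays. The comparison of late with early effects in each line carries the same limit. Late minus early, 4897 genes changed in BEAS-2B, 1766 up and 3131 down, and 4837 in HCT116, 1718 up and 3119 down. Without the step that equalises arrays the median of all genes moved to -0.15 in BEAS-2B and -0.36 in HCT116. In BEAS-2B RASD1 rose further by 6.30, while FZD2 stood at -3.35, SLF2 at -3.21, SLC61A1 at -3.16 and LRRC17 at -3.15. RASD1 was detected on 1 of 2 untreated arrays at each stage, and on the late copper arrays 3 of 4 detected SLF2 and 1 of 4 SLC61A1 and LRRC17. RGS2, the Notch ligand gene DLL1, GADD45G and ZCCHC12 were called higher and MIR503HG lower there. No size is given for these 5, since the first 4 were undetected on the untreated arrays of 12 and 18 h and MIR503HG on the copper arrays. The same holds for GADD45G, HSPA6, RRAD, HSPA1A and HSPA7 in HCT116, each called higher and undetected on the untreated arrays of 12 and 18 h. DDIT4 was lowest at -4.96 ± 0.18, then HS3ST1 at -4.53, the stress cytokine gene GDF15 at -4.23, IRF2BPL at -3.94 and DHX32 at -3.92, with HS3ST1 and DHX32 detected on 3 of the 4 late copper arrays.

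Late minus early, heat shock genes gave 19 rises and 0 falls in BEAS-2B (list adjusted p = 3.9e-12) and 22 and 0 in HCT116 (list adjusted p = 1.4e-15), with the small heat shock gene CRYAB at 4.07 in BEAS-2B and called higher in HCT116, where it was detected on the copper arrays of 12 and 18 h and on no other array of this comparison. Metallothioneins rose further in HCT116, with 5 rises and 0 falls (median 1.56, list adjusted p = 2.9e-05) and MT1F at 1.78. Their mean there was 1.19, and 0.61 against all untreated arrays (list adjusted p = 0.0093). Their 4 rises in BEAS-2B gave a list p of 0.067, of 0.028 without replicate 1 of the copper arrays at 12 h, and of 0.038 without the detection filter. ATF4 targets gave 11 rises and 4 falls in BEAS-2B (list adjusted p = 7.8e-04), with PSAT1 at 1.09. In HCT116 they gave 3 rises, 13 falls and 8 not called (3 and 14 adjusted over the list alone; median -0.44, list adjusted p = 0.0021, adjusted p = 0.062 with an estimated correlation), with STC2 at -2.56 and CEBPB at -2.30, and against all untreated arrays their mean was 0.17 (list adjusted p = 0.19). Hypoxia targets gave 1 rise and 13 falls in HCT116 (1 and 14 adjusted over the list alone; list adjusted p = 8.5e-05), with ADM at -2.18, and against all untreated arrays the list p was 0.75. Mesenchymal markers gave 7 falls and 0 rises in BEAS-2B (median -0.64, list adjusted p = 0.0024), with COL1A1 at -2.03 and PDGFRB at -1.70. Colon markers gave 7 falls and 0 rises in HCT116 (1 rise adjusted over the list alone; median -0.79, list adjusted p = 0.020), with ELF3 at -2.94 and with CDX2 called lower but undetected on the copper arrays of 12 and 18 h, and against all untreated arrays the list p was 0.22 and without the between-array step 0.053.

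The comparison of the lines asks where the average copper effect of HCT116 differed from that of BEAS-2B, at doses that also differed. As lists, targets of ATF4, hypoxia genes and NF-kB genes were lower in HCT116 relative to BEAS-2B, and YAP and cytoskeletal genes and proteasome genes were higher. In all, 3873 genes differed, 1883 higher and 1990 lower in HCT116, of which 144 and 454 differed by more than 2-fold. ANKRD1 was higher in HCT116 relative to BEAS-2B at 3.94 ± 0.27 (adjusted p = 4.6e-09), but in HCT116 it was detected on 1 of 6 untreated and 8 of 10 copper arrays, so the size is uncertain. Also higher were the matrix gene THBS1 at 3.52, and the matricellular genes CCN2 at 3.47 and CCN1 at 3.12. ANGPTL4 was lowest at -4.15 ± 0.26 from probes of unlike size, then KLF4 at -3.56, TRIB1 at -3.55 and SOX4 at -3.41, with KLF4 detected on 4 of 6 untreated BEAS-2B arrays. MT1B was called higher and the protease gene MMP3 and MT1M lower, but MT1B was undetected on every BEAS-2B array of this comparison and the other pair on every HCT116 array, so no size is given for them. Among other early response genes, JUN was at 2.82 and EGR1 at 2.38. HMOX1 was at -2.05, MT1X at -1.47 and PMAIP1 at -2.05. HSPA1B was at -2.12, while HSPA1A was called higher in HCT116, where it was undetected without copper, and since these paralogs encode the same protein and differ by few bases, their opposite signs may lie in the probes.

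ATF4 targets rose less in HCT116, with 19 lower, 1 higher and 4 not called, also when adjusted over the list alone (median -0.49, list adjusted p = 3.4e-11), including DDIT4 at -1.97, TRIB3 at -1.79 and CTH at -1.43. The mean difference was -0.65, and -0.51 against all 8 untreated arrays of each line (list adjusted p = 1.0e-07). At 2 and 4 h the list means were 1.08 in BEAS-2B and 0.96 in HCT116, with DDIT4 at 3.34 and 3.46. At 12 and 18 h the means were 1.51 and 0.18. By then untreated HCT116 levels had stepped up, by 4.10 for DDIT4 and 1.94 for TRIB3, so part of the difference lies in untreated arrays. Hypoxia targets gave 15 lower, 0 higher and 3 not called, also when adjusted over the list alone (median -0.63, list adjusted p = 3.4e-11), with NDRG1 at -2.53, PFKFB4 at -1.95 and HK2 at -1.90. Their mean difference was -0.87, and -0.76 against all 8 untreated arrays of each line (list adjusted p = 6.9e-08). Their means were 0.60 in BEAS-2B and 0.27 in HCT116 at 2 and 4 h. At 12 and 18 h, after the same step in untreated HCT116, they were 1.01 and -0.60. NF-kB genes gave 10 lower, 2 higher and 6 not called (12 and 2 adjusted over the list alone; median -0.62, list adjusted p = 3.8e-04), with NFKBIZ at -2.35, and with CXCL2 called lower and CCL2 higher, both undetected on every HCT116 array of this comparison. In HCT116 7 NF-kB genes were not measured on both sides, against 2 in BEAS-2B. The HCT116 median of 0.11 became 0 with members set to their bounds, so much of this list lay near background there. YAP and cytoskeletal genes gave 7 higher, 1 lower and 9 not called (10 and 1 adjusted over the list alone; median 0.30, list adjusted p = 1.7e-06). Those higher were the matricellular genes CCN1, CCN2 and THBS1, the YAP target genes ANKRD1 and AXL, the latter at 0.61, and the genes TAGLN at 2.95 and MYL9 at 0.88, whose products bind actin or myosin. The actin genes ACTB, ACTG1 and ACTA2 and the genes VCL and TPM1 were not called (adjusted p of 0.061 to 0.38), and CNN1 was undetected on every HCT116 array of this comparison. ACTB was called without the 2 h arrays (adjusted p = 0.028), and ACTA2 without those of 12 or 18 h (adjusted p = 0.017 and 0.022). Without replicate 1 of copper-treated HCT116 at 2 h both were called (adjusted p = 0.042 and 0.034), and ACTB also without replicate 2 of 12 h or 1 of 18 h of these arrays or replicate 2 of untreated HCT116 at 6 h (adjusted p of 0.014 to 0.044). CCN2 started high in BEAS-2B, at 13.79 ± 0.33 (SD, n = 8) on untreated arrays against 6.92 ± 0.79 (SD, n = 8) in HCT116. Proteasome genes gave 13 higher, 1 lower and 13 not called (16 and 1 adjusted over the list alone; median 0.24, list adjusted p = 1.2e-04), with PSMA2 at 0.99 and PSMD1 at 0.42, the latter not called without the 12 h or 18 h arrays (adjusted p = 0.072 and 0.15). Heat shock genes gave 6 higher, 13 lower and 10 not called (7 and 15 adjusted over the list alone; median -0.22, list adjusted p = 0.045, adjusted p = 0.14 with an estimated correlation), with CHORDC1 at -1.07, and with HSPA6 called lower but undetected without copper in HCT116. That call sat at the threshold. It was lost without the arrays of 2, 4 or 6 h, at list p of 0.10, 0.056 and 0.11, and without any of 10 single copper arrays, at list p of 0.050 to 0.062. These were replicate 1 of 4 h, 6 h and 18 h and replicate 2 of 12 h in BEAS-2B, and replicate 1 of 2 h, replicate 2 of 4 h and both replicates of 12 h and 18 h in HCT116. The call was lost as well with the strict detection filter and the mean of a gene's probes, at list p of 0.068 and 0.097. Without the 4 h arrays the immediate early list was called (mean -0.32, list adjusted p = 0.028), and without the 18 h arrays the mitosis list (mean 0.19, list adjusted p = 0.0085). The mitosis list was also called with quantile normalization alone, the deposited normalized values and all untreated arrays, at list p of 0.033, 0.033 and 0.010. With all arrays the other 19 lists were not called, among them metallothioneins (list adjusted p = 0.40) and NRF2 targets (list adjusted p = 0.13, with a median of 0.02 and a mean of -0.22).

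**Figure D3:**
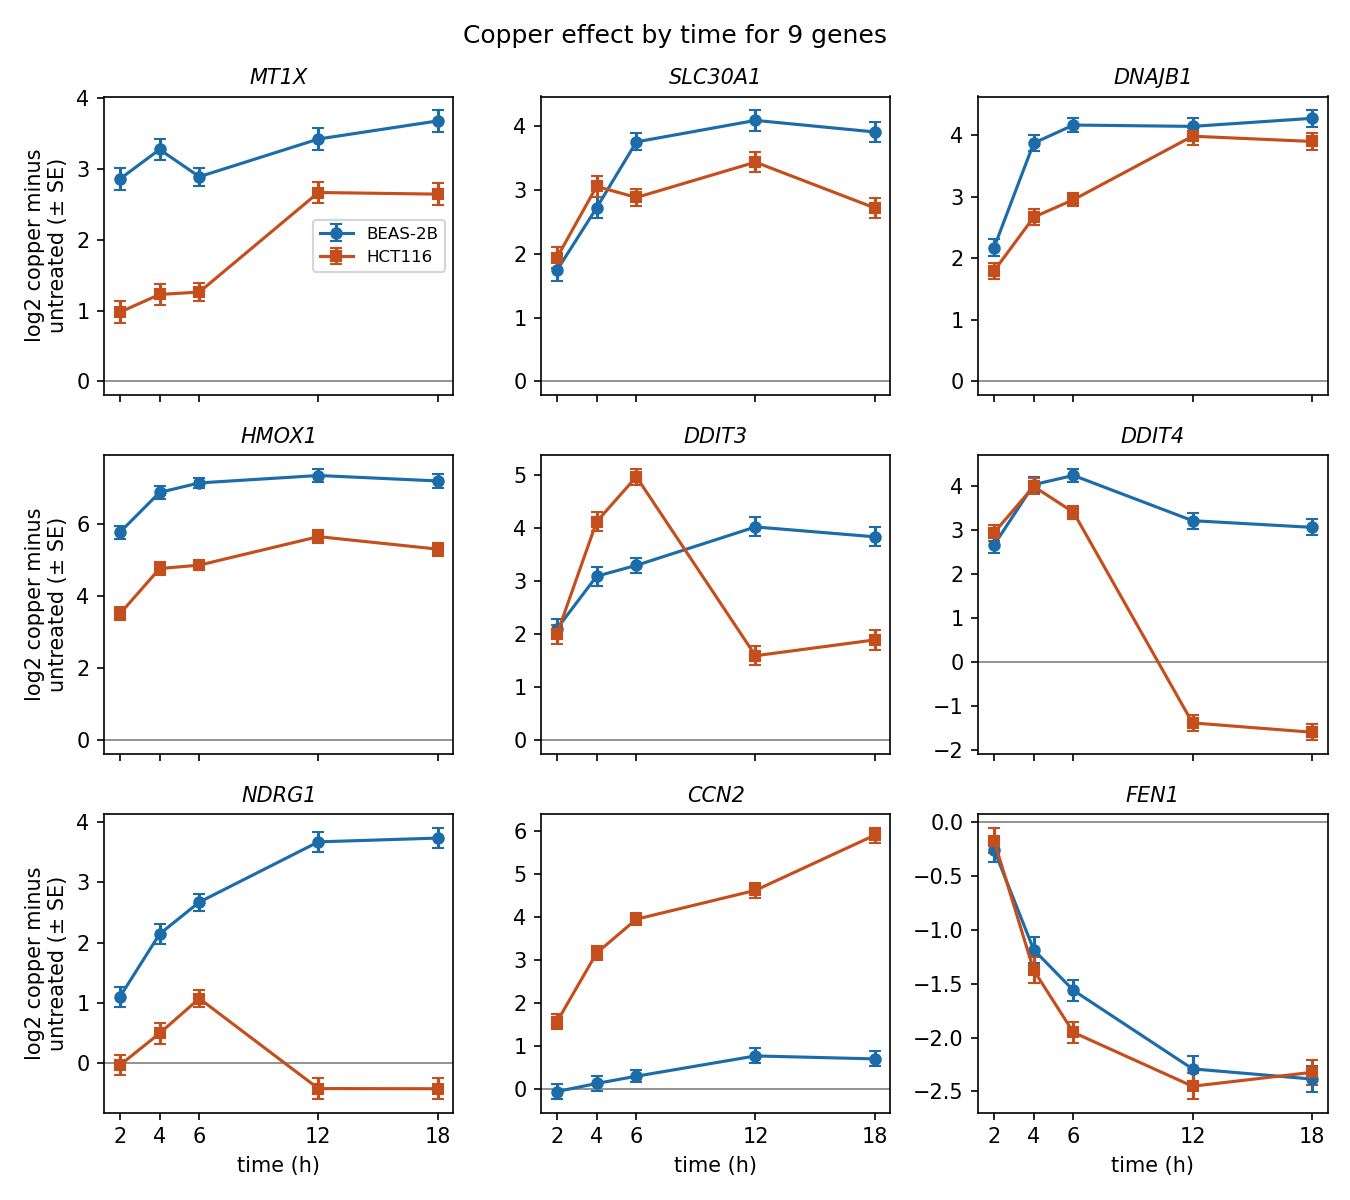
Each panel shows the log2 difference, copper minus untreated (vertical, ± SE), against time (h, horizontal) for a gene in BEAS-2B (circles) and HCT116 (squares). DDIT4 stays at 2.66 or more in BEAS-2B and falls from 3.40 at 6 h to -1.39 at 12 h in HCT116, and CCN2 climbs from 1.58 to 5.91 in HCT116.

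The comparison of later untreated arrays with those of 0 h asks what changed in culture without copper. In BEAS-2B FOS and EGR1 fell after 0 h, and 5 of the metallothionein genes named below rose. In HCT116 DDIT4, GDF15 and DDIT3 rose. Over 2 to 18 h against 0 h, 41 genes changed in BEAS-2B, 16 up and 25 down, and 84 in HCT116, 51 up and 33 down. These counts move with single arrays and times. Without replicate 1 or 2 of the untreated BEAS-2B arrays at 0 h the first was 19 or 12, without replicate 2 of those at 6 h 26, without the 6 h arrays 15 and without the 18 h arrays 62. Without replicate 1 or 2 of the untreated HCT116 arrays at 0 h the second was 25 or 45, without the 12 h arrays 1, without the 18 h arrays 2, and without the 2 h and 4 h arrays 169 and 178. FOS was at least 8.3-fold lower after 0 h in BEAS-2B, EGR1 fell to -3.03 ± 0.09, CCDC190, detected on 5 of 6 later arrays, to -1.10, ZFP36 to -1.08 and NFKBIZ to -1.05. MT1F rose by 1.56 ± 0.09, ANGPTL4, detected on 1 of 2 arrays of 0 h, by 1.48, MT1X by 1.28, MT1E by 1.12, MT1G by 1.03, MT2A by 0.88 and SLC30A1 by 0.83. Without replicate 2 of 0 h, MT1E, MT1G, MT2A, SLC30A1, CCDC190 and NFKBIZ were no longer called (adjusted p = 0.15, 0.14, 0.086, 0.052, 0.28 and 0.13), and without replicate 1 the last pair was not (adjusted p = 0.17 and 0.16). Without the 6 h arrays CCDC190, MT1E and NFKBIZ were not called (adjusted p = 0.15, 0.096 and 0.064), nor SLC30A1 without those of 2 h (adjusted p = 0.065). In HCT116 DDIT4 rose by 1.74 ± 0.12, GDF15 by 1.52, DDIT3 by 1.33, ANKRD37 by 1.23 and ULBP1 by 1.22. THBS1 fell to -1.34 ± 0.14, FAM210A to -0.92, DMRT1 to -0.87, F3 to -0.85, MRAS, detected on 1 of 6 later arrays, to -0.82 and SLC30A1 to -0.58. Without replicate 1 of 0 h, ANKRD37, ULBP1, FAM210A, DMRT1, F3 and SLC30A1 were not called (adjusted p = 0.15, 0.065, 0.051, 0.11, 0.16 and 0.39), nor DMRT1 without replicate 2 (adjusted p = 0.15). Of these 11 genes DDIT4 alone was called without the 12 h arrays, and DDIT4 and DDIT3 without the 18 h arrays. ANGPTL4 in BEAS-2B was not called without the 2, 4 or 6 h arrays, or without either replicate of untreated BEAS-2B at 0 or 6 h, of copper-treated HCT116 at 4 h or of untreated HCT116 at 6 h (adjusted p of 0.051 to 0.53). MRAS was not called without the 6 h arrays, either replicate of untreated HCT116 at 0 h, replicate 2 at 6 h, or either replicate of BEAS-2B with copper at 2 h or untreated at 0 or 6 h (adjusted p of 0.051 to 0.41).

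MRAS and DMRT1 were lower from 2 h on, going from 5.55 and 6.48 at 0 h to 4.69 and 5.85 at 2 h and to 4.55 and 5.45 at 12 h. Others changed mainly after 6 h, and this step was tested after the levels had been seen. Untreated arrays of 12 and 18 h differed from those of 0 to 6 h in 2225 genes in HCT116, 1168 up and 1057 down, and in 494 genes in BEAS-2B, 213 up and 281 down. On untreated HCT116 arrays DDIT3 stood at 6.29 at 6 h and 9.67 at 12 h, GDF15 at 7.88 and 11.32, TRIB3 at 9.64 and 11.73, VEGFA at 6.00 and 7.68, and THBS1 at 8.81 and 5.53. ATF4 targets gave 18 rises and 0 falls in this step (median 0.67, list adjusted p = 2.2e-20; where 1 pair of counts is given it was the same adjusted over the list alone) and hypoxia targets 12 and 2 (median 0.64, list adjusted p = 4.8e-09). Metallothioneins gave 6 falls and 0 rises (median -0.52, list adjusted p = 4.7e-05) and YAP and cytoskeletal genes 5 and 0 (8 and 1 adjusted over the list alone; list adjusted p = 1.1e-05), so part of their late copper difference in HCT116 lies in the untreated arrays. In that line 8 heat shock genes fell with 0 rises (list adjusted p = 0.0065, adjusted p = 0.057 with an estimated correlation). Mitosis genes gave 11 rises and 1 fall (12 and 3 adjusted over the list alone; list adjusted p = 1.5e-04, adjusted p = 0.098 with an estimated correlation). Their late copper mean in HCT116 was -1.23, and -1.01 against all untreated arrays of the line. Cholesterol synthesis genes gave 5 and 0 (7 and 0; list adjusted p = 0.0497, adjusted p = 0.076 with an estimated correlation). In BEAS-2B the step held 15 falls and 0 rises among immediate early genes (list adjusted p = 1.9e-24) and 9 rises and 0 falls among cholesterol synthesis genes (13 and 0 adjusted over the list alone; list adjusted p = 3.9e-14). NF-kB genes gave 4 falls and 0 rises there (7 and 0 adjusted over the list alone; list adjusted p = 5.3e-08), with CXCL8 at -2.64 and IL11 at -1.57. ATF4 targets gave 5 and 1 (9 and 2; list adjusted p = 3.0e-04). Ribosome biogenesis genes gave 3 falls and 0 rises (6 and 0; list adjusted p = 1.5e-06). DNA replication genes gave 2 rises and 0 falls (6 and 0; list adjusted p = 2.9e-04). BCL2 genes gave 6 falls and 1 rise (list adjusted p = 0.042, adjusted p = 0.063 with an estimated correlation). YAP and cytoskeletal genes gave 3 and 0 (4 and 1; list adjusted p = 0.042, adjusted p = 0.25 with an estimated correlation). Histones gave 2 rises and 0 falls (list adjusted p = 0.0087, adjusted p = 0.063 with an estimated correlation).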

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

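The test of copper-treated material in untreated arrays, the grouping of genes by signal over all arrays and the matching of unnamed probes by signal were chosen only after the result was seen. For the late fall of most called genes, for metallothioneins in untreated BEAS-2B and for YAP genes in HCT116, technical explanations are set against biological ones.

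Late in copper, falls made up 63.2% of the calls in BEAS-2B and 63.1% in HCT116. Quantile normalization as the whole cause is argued against, since without that step falls made up 68.6% and 71.4%. A loss of dim genes on copper arrays is argued against by the brightest of 4 equal groups of genes by signal over all arrays. There falls made up 65.5% of late calls in BEAS-2B and 61.5% in HCT116. By untreated signal, the grouping set beforehand, the brightest group had 72.4% and 70.1% falls and the dimmest 14.0% and 23.5%. That grouping uses 1 side of the difference, which tilts bright genes to falls and dim genes to rises, so it cannot decide. A scaling of the arrays before the deposit stays open, because every array held nearly the same mean, and with it a lower RNA content per cell that no array here could show. A drop of many transcripts under long copper exposure, relative to the rest, may remain as a hypothesis, and the cause was not tested.

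Of 10 genes tested among metallothioneins and SLC30A1, 7 rose in untreated BEAS-2B after 0 h, by a median of 1.03 on the log2 scale. MT1X went from 8.64 at 0 h to 10.61 at 6 h and 9.19 at 18 h, and SLC30A1 from 7.29 at 0 h to 9.13 at 2 h and 6.98 at 18 h. Copper-treated material in the later untreated arrays is argued against, because the 20 genes with the largest early copper effect had a median change of -0.044 with a standard error of 0.21, with HSPA6 at 0.18 and HMOX1 at 0.00021. A deviant array at 0 h is argued against by a median gap of 0.21 between the arrays of 0 h over the 7 genes, although without replicate 2 of 0 h the calls of MT1E, MT1G, MT2A and SLC30A1 were lost at rises of 1.02, 0.89, 0.77 and 0.81. Metal in fresh medium could give such a rise and was not tested, and in HCT116 the same contrast gave -0.32 for MT1X and -0.58 for SLC30A1.

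The list of YAP and cytoskeletal genes was higher in HCT116, with a median difference of 0.30. Of 17 members 8 differed, 7 of them higher. Single untreated arrays as the cause stay open, since the check against all 8 of each line includes them (list adjusted p = 4.3e-05). The alternatives ranged from 4.7e-08 to 0.014. From earlier to late untreated HCT116 arrays the list itself fell (list adjusted p = 1.1e-05). A ceiling of the signal in BEAS-2B stays open, since the members that differed had a median of 12.79 on untreated and 12.81 on copper arrays of that line, where the highest value on any array was 14.36. ANKRD1, AXL and MYL9 speak against a ceiling for themselves alone, as they went from 9.21 to 7.71, 13.04 to 12.66 and 10.95 to 10.88 in BEAS-2B. Line and dose cannot be told apart, so the difference may be one of dose.

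The average copper effect differed between the lines in 3873 genes by the test of the difference. Swapping the line labels of whole times gave at most 3447 genes in the other swaps, with 1 of 16 as large as the real count, and 16 swaps are too few for a share under 0.05. Regrouping copper and untreated arrays within each time gave at most 5545 genes in BEAS-2B against the real 7162, and 1 of 100 regroupings, the real one, was as large. In HCT116 the highest other count was 5668 against 6818, again with 1 of 100. For both counts this argues against a chance placement of arrays within times, and a regrouping can leave some of the times as they were. Chance differences between cultures cannot be excluded this way, since the labels do not say whether arrays of a group came from separate cultures.

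By the same test of the difference between the lines, the median was -0.22 for heat shock genes (adjusted p = 0.14 with an estimated correlation, and no call without the arrays of 2, 4 or 6 h, without any of 10 single copper arrays, with the strict filter or with the mean of a gene's probes), -0.49 for ATF4 targets, -0.62 for NF-kB genes, -0.63 for hypoxia targets and 0.24 for proteasome subunits. The genes with the largest differences were ANKRD1 at 3.94, MT1B at 3.60, THBS1 at 3.52, CCN2 at 3.47 and CCN1 at 3.12, and ANGPTL4 at -4.15, MMP3 at -3.92, KLF4 at -3.56, TRIB1 at -3.55 and SOX4 at -3.41. MT1B was undetected on the BEAS-2B arrays and MMP3 on the HCT116 arrays of this comparison, so their values are not measured sizes. ANKRD1 was detected on 1 of 6 untreated HCT116 arrays, so its size is uncertain.

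Probes without a gene name were outside the gene counts and also carried signal. Of 7095 that passed the detection filter, 1930 were called late in BEAS-2B, 1202 of them as rises (62.3%), and 1955 in HCT116, 1280 of them as rises (65.5%). Named probes of like signal had 38.3% and 38.5% rises among their late calls.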

How the results depend on the processing

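Leaving out each time and the background correction without detection p-values were tests chosen only after the data were seen. The counts of genes changed by copper on average, late, late minus early and between the lines stayed within 1.5 times their values under every alternative run. So did the early counts, except against all untreated arrays of a line, where they were 4617 in BEAS-2B and 3089 in HCT116, with more reference arrays behind each value, and with each line fitted alone, where the HCT116 count was 756.

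The counts for later untreated arrays against 0 h, 41 in BEAS-2B and 84 in HCT116, moved most. They were 92 and 151 with quantile normalization alone, 92 and 151 with the deposited normalized values, 26 and 50 without the between-array step, 121 and 202 with array weights, and 76 and 162 with a trended and robust variance. The replicate block gave 26 in BEAS-2B, and HCT116 fitted alone gave 5. Without the 6 h arrays BEAS-2B gave 15 and without those of 18 h 62. HCT116 gave 169 without the 2 h, 178 without the 4 h, 1 without the 12 h and 2 without the 18 h arrays, and the 12 and 18 h arrays are those where its untreated levels had stepped. The cause was not tested for the others.

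Leaving out single arrays of groups of 2 gave 12 to 47 genes for untreated BEAS-2B, with 12 and 19 without an array of 0 h and 26 without replicate 2 of 6 h, and 25 to 110 for untreated HCT116, with 25 and 45 without an array of 0 h. The other counts ranged from 6932 to 7337 and from 6604 to 7018 for the averages of BEAS-2B and HCT116, from 1927 to 2628 and 983 to 1527 early, from 7033 to 7444 and 6955 to 7203 late, from 4588 to 5135 and 4562 to 5110 for late minus early, and from 3640 to 4137 between the lines. The array left alone in its group is assumed to vary like the others.

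For gene lists, 9524 results under alternatives kept side of the threshold and, if called, direction. A call was lost by 83, gained by 67 and reversed by 1, the mean of ATF4 targets for late minus early in HCT116. It was 0.17 against all untreated arrays. Early and late effects there share 1 reference, which cancels, so higher untreated levels of these genes at 12 and 18 h have no part. For the genes named, 15686 kept side and any called direction, 89 lost a call, 23 gained one and 1 reversed. This was ATP7B on average in HCT116, at 0.049 with the mean of its probes, some of other sign. Of these lost or gained, the genes other than those of the untreated contrasts were ATP7B, PSMD1, PDGFRB early in BEAS-2B (adjusted p = 0.052 without the between-array step, in alternatives up to 0.075), HAS3 early in HCT116 (adjusted p = 0.058 with the line fitted alone), HES1 late in HCT116 (called at 1.06 against all untreated arrays), and 4 genes between the lines. Of these ACTB was called under 10 alternatives, at 0.19 to 0.41, and ACTA2 under 6, at 0.30 to 0.45. With the mean of a gene's probes ACTG1 was called at 0.31 and TPM1 at -0.41. The slide as a block was not run.

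Without the between-array step the median over all genes lay at -0.11 late in BEAS-2B, -0.19 late in HCT116, and at -0.15 and -0.36 for late minus early, so changes are relative to the other genes of an array. In the contrasts with copper the share of falls moved by more than 10 points once, for late minus early in HCT116 without that step, from 64.5% to 75.7%. For untreated BEAS-2B arrays falls were 25 of 41 calls, and 24 of 31 without the 2 h, 23 of 51 without the 12 h and 28 of 62 without the 18 h arrays, and 9 of 12 without replicate 2 of 0 h. For untreated HCT116 arrays they were 33 of 84, and 1 of 5 with the line fitted alone, 0 of 1 and 0 of 2 without the 12 and the 18 h arrays, and 23 of 45 without replicate 2 of 0 h. Of 4018 genes with several tested probes, 2305 were called on average in BEAS-2B, and 531 of these had probes of opposite sign. In HCT116 these counts were 2158 and 590. Signal over background limits the late contrasts, where 37.0% of probes in BEAS-2B and 34.7% in HCT116 were detected on copper arrays.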

Other observations

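The correlations with gene span at 2 and 4 h, and the 12 families of gene symbols, whose name patterns were narrowed after first values were seen, are tests chosen only after the result was seen.

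It was asked whether genes of short genomic span fell more late in copper. Across 14665 genes, which are not independent replicates, Spearman's rho between the late effect and the log10 of the span was -0.04 in BEAS-2B and -0.053 in HCT116, where the hypothesis needed a value above 0.1 in both. At 2 and 4 h rho was 0.162 and 0.0757. Genes that fell at 2 and 4 h had a median span of 14.3 kb in BEAS-2B and 14.9 kb in HCT116, against 27.3 and 27.1 kb for genes not called and 32.7 and 23.0 kb for genes that rose.

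Families were tested with camera at 2 and 4 h and at 12 and 18 h in each line, with adjustment over the 12 families. Small nucleolar and Cajal body RNAs gave 72 rises and 11 falls among 183 at 12 and 18 h in BEAS-2B (median 0.28, adjusted p = 3.1e-07) and 90 and 9 in HCT116 (median 0.53, adjusted p = 1.3e-10). SNORD14D stood at 4.81 and 4.34, SNORA57 at 4.70 and 1.88, and SNORA28 at 3.42 and 4.42. At 2 and 4 h they gave 38 rises and 6 falls in HCT116 (adjusted p = 1.1e-10) and 14 and 16 in BEAS-2B (adjusted p = 0.46). The family rose late in all 5 scalings of the data in both lines.

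Histone genes as a whole family of 53 gave 30 rises and 3 falls late in BEAS-2B (median 0.74, adjusted p = 3.6e-09) and 30 and 2 in HCT116 (median 0.65, adjusted p = 1.4e-08), with H2AC18 at 5.66 and 3.98, H2AC20 at 4.82 and 3.04 and H1-10 at -2.49 and -2.66. Cancer-testis genes gave 14 rises and 0 falls among 42 in BEAS-2B (median 0.15, adjusted p = 2.3e-05) and 16 and 1 in HCT116 (median 0.31, adjusted p = 8.1e-05). Both medians kept their sign in all 5 scalings.

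Mitochondrial ribosomal proteins fell from the start, with 40 falls and 0 rises among 76 at 2 and 4 h in BEAS-2B (adjusted p = 1.7e-16) and 13 and 0 in HCT116 (adjusted p = 7.6e-09). Late in copper they gave 54 falls and 5 rises in BEAS-2B (median -0.63, adjusted p = 1.7e-06) and 46 and 6 in HCT116 (median -0.43, adjusted p = 1.4e-04, and adjusted p = 0.12 with an estimated correlation). MRPS26 stood at -2.52 and -3.04 and MRPL17 at -2.00 and -2.19, and the late medians were below 0 in all 5 scalings. Subunits of NADH dehydrogenase gave 12 falls and 0 rises among 34 at 2 and 4 h in BEAS-2B (adjusted p = 9.4e-06, and adjusted p = 0.10 with an estimated correlation) and 3 and 0 in HCT116 (adjusted p = 0.0097, and adjusted p = 0.41 with an estimated correlation). Their late counts were 19 falls and 1 rise in BEAS-2B (adjusted p = 0.0019, and adjusted p = 0.17 with an estimated correlation) and 11 and 2 in HCT116 (adjusted p = 0.39).

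At 2 and 4 h ID, HES and HEY genes gave 2 rises and 4 falls among 11 in HCT116 (median -0.45, adjusted p = 0.0097) and 2 and 1 in BEAS-2B (adjusted p = 0.46). They gave 6 rises and 3 falls late in BEAS-2B (median 1.03, adjusted p = 0.0010) and 3 and 5 in HCT116 (median 0.14, adjusted p = 0.61), where the median fell to -0.04 without the between-array step and to -0.0079 with the background correction that does not use detection p-values. ID2 stood at 5.53 and 2.31, HES1 at 4.00 and 0.24, and ID1 at 2.28 and -2.73. Matrix metalloproteinase genes gave 4 rises and 0 falls among 16 at 2 and 4 h in BEAS-2B (adjusted p = 0.015). Late in copper they gave 7 and 2 in BEAS-2B (adjusted p = 0.0025) and 5 and 3 in HCT116 (adjusted p = 0.30), with MMP3 at 6.15 and MMP1 at 5.66 in BEAS-2B, the latter detected on 1 of 2 untreated arrays. The differences between the lines were not tested for these families. DUSP genes gave 7 rises and 1 fall among 23 at 2 and 4 h in BEAS-2B (adjusted p = 0.0047) and 5 and 1 in HCT116 (adjusted p = 0.0097). Late in BEAS-2B they gave 7 and 4 with a median of -0.03 (adjusted p = 0.042, and adjusted p = 0.051 with an estimated correlation), and late in HCT116 5 and 8 (adjusted p = 0.59). The other families, zinc finger, HOX, keratin and mitochondrial carrier genes, were not called early or late in either line.

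Of 19 mesenchymal markers on the array, 15 were detected on all 8 untreated BEAS-2B arrays and 4 on all 8 of HCT116. Of 17 colon markers the counts were 4 and 7, of 10 basal airway markers 4 and 5, and of 11 leukocyte markers 3 and 2. VIM stood at 13.85 ± 0.10 (SD, n = 8) in BEAS-2B and 7.43 ± 0.15 (SD, n = 8) in HCT116, and EPCAM at 5.43 ± 0.21 (SD, n = 8) and 13.05 ± 0.12 (SD, n = 8). CDH1, the gene of epithelial cadherin, was detected on 0 of the 8 BEAS-2B and on all 8 of the HCT116 arrays. PTPRC, a marker of leukocytes, was detected on 0 and 1 of the 8 arrays.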
